A study of Mus musculus with 10 samples.

How the data were processed

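Gene expression was measured in whole mouse placentas of embryonic day 12.5 on Affymetrix Mouse430_2 arrays, with 1 array per sample and 10 arrays in all. The deposited values were probe set intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes. MAS5 summarises the probes of a set as a signal in arbitrary units. Its version and settings are not given in the sources used here. The mean of each array after trimming 2% of probe sets at each end was 100, so the authors' scaling between arrays was kept. The table held 45101 probe sets, and no detection calls were used here. One other kind of deposited record, the instrument's text file for each array, was used only to find batches. It has no unit of expression.

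The labels put each sample in a group in ways that conflicted. The title and the sample description gave the genotype one way, and the source name gave the opposite genotype for all 10 arrays. Groups were taken from the title, with 5 knockout and 5 wild-type arrays, and this choice was made before the data were examined, as were the tests between the groups, the gene lists and the rule for named genes. The alternatives named as such below and the tests of closeness between strongly changed genes were chosen after seeing the data.

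The 64 AFFX control probe sets and 1 probe set with a missing value were left out, leaving 45036. Probe sets were named from the platform annotation, where 34944 had 1 gene symbol, 932 had several and 9160 had none. No gene was named from a probe set with several symbols. Signals were converted to log2(signal + 16), which understates the fold change of dim probe sets. Probe sets with a mean log2 value under the 40th percentile were left out, leaving 27022, and the dimmest of these had a mean log2 value of 4.89. Knockout minus wild type was fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Where several probe sets named a gene, the one with the brightest mean stood for it, and a probe set ending in _x_at was taken only where there was no other. This gave 12713 genes.

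The 27 fixed gene lists held 451 different genes, of which 382 were tested. They covered placental cell types, other cell types that a dissected placenta can hold, and pathways. The 26 lists with at least 3 tested genes were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, with fry, and with an exact two-sided permutation test of the list means. The list of Y-linked genes fell below that minimum and was described by its values. An exact test of 5 arrays against 5 cannot give a p below 0.00794. Genes named in the text were Pcdh12, the 15 highest and 15 lowest log2 fold changes among called genes with all 5 knockout arrays on one side of the wild-type mean, up to 4 members of each list with the smallest p, and the sex-linked genes. Of the lists' genes, examples with their values are given from that set.

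For the region around Pcdh12, gene order and chromosomes were taken from the RefSeq genes of GRCm38. The array files named no genome build, so no coordinates were used, and the planned window in base pairs was replaced by the planned fallback of 100 protein-coding neighbours on each side. RNA quality was followed by the ratio of 3-prime to 5-prime control probe sets of Gapdh and Actb.

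The instrument records named 3 chip lots and gave a hybridization date and time for each array. Cutting these times at gaps of over 60 minutes gave 4 groups of arrays, which are called wash runs here. In each of the 2 runs that held both groups there were 2 knockout and 2 wild-type arrays. Knockout replicate 3 was run alone on an earlier day with a lot of its own, and wild-type replicate 5 was run alone. Of the 2 lots that held both groups, one held 1 knockout and 4 wild-type arrays and the other 3 knockout and 1 wild-type. Wash run and chip lot were fitted as blocks. Other alternatives were the pseudocount (1 and 64), no filter and a filter at the 70th percentile, centring on the median, quantile normalization, no intensity trend, array weights, the Y-linked genes as a covariate, a replicate block, other probe set rules, an exact rank sum test and leaving out each array in turn. Fits within 1 wash run or 1 chip lot, a fit without knockout replicate 3 and wild-type replicate 4, and a fit with the mean of the decidua list as a covariate, were chosen after seeing the data.

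The steps were tested on simulated data for knockout minus wild type, with the means and spreads of the 27022 probe sets and 200 of them changed. At a change of 1 log2 unit, 59% of the 100 changed probe sets were recovered, and at 0.5 log2 units 8%, with 1 false call. In a simulation over 12713 genes with 1 list shifted by 0.5 log2 units, camera called that list and 1 of the others. Noise was drawn independently for each gene and array in both simulations, so they held no correlation between genes and no batches. They therefore cannot check the preset correlation of camera, or the rate of false calls, for the real arrays. The simulation also changed far fewer probe sets than the 2582 called in the real data. The cut-off of the adjustment depends on that share, so the recovered percentages do not carry over to the real arrays.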

Results

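Protocadherin 12 (Pcdh12) is a cell adhesion protein of the cadherin superfamily. To find genes whose expression depended on it, RNA from whole placentas of embryonic day 12.5 was compared between Pcdh12 knockout and wild-type mice, with 5 arrays in each group. The median signal of the 10 arrays lay between 22.4 and 27 units, and the number of arrays limits the precision. Per the series text, the RNA came from 5 knockout and 5 normal placentas, and the p-values below measure only the spread between these samples.

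Pcdh12 signal was lower in the knockout arrays on 2 of its 3 probe sets. Probe set 1437928_at, the brightest, had a signal of 74 ± 6.05 in knockout and 182 ± 66.3 in wild-type placentas (SD, n = 5 each; log2 fold change -1.08, SE 0.19, limma adjusted p = 0.0038). On 1450473_at the signal was 6.92 ± 6.26 against 65 ± 21.1, a log2 fold change of -1.82 (SE 0.21, limma adjusted p = 0.000269). Its knockout mean lay below 13.6 units, the level of the filter, so the size of that change is uncertain. All 5 knockout arrays lay below all 5 wild-type arrays on both probe sets, which gave an exact two-sided permutation p of 0.00794, the smallest this design allows. The third probe set, 1440023_at, was dim and went the other way, with 28.4 ± 6 in knockout and 16.1 ± 5.26 in wild type (log2 fold change 0.47, limma adjusted p = 0.097, exact two-sided permutation p = 0.0238). Which of these probe sets lie in the deleted part of the gene is not given in the sources used here, and a probe set outside it would not check the labels. The direction on the first pair of probe sets goes with the genotype in the titles and against that in the source names. With the chip lot as a block the fold changes were -1.19 (adjusted p = 0.0523) and -1.73 (adjusted p = 0.0197), and with the wash run as a block -1.05 (adjusted p = 0.0352) and -1.87 (adjusted p = 0.0044). Within the 2 wash runs that held both groups the brightest probe set gave -0.91 (limma adjusted p = 0.0334) and -1.18 (0.46, not called). On 1450473_at the runs gave -1.53 (0.0387) and -2.21 (0.0836, not called). Within the 2 chip lots, each with 1 array in one group, the values were -1.16 and -1.22 on the brightest and -2.06 and -1.37 on 1450473_at. With the mean of the decidua list, which marks maternal stroma, as a covariate, an alternative chosen after seeing the data, the brightest probe set gave -0.69 (adjusted p = 0.0248).

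**Figure D1:**
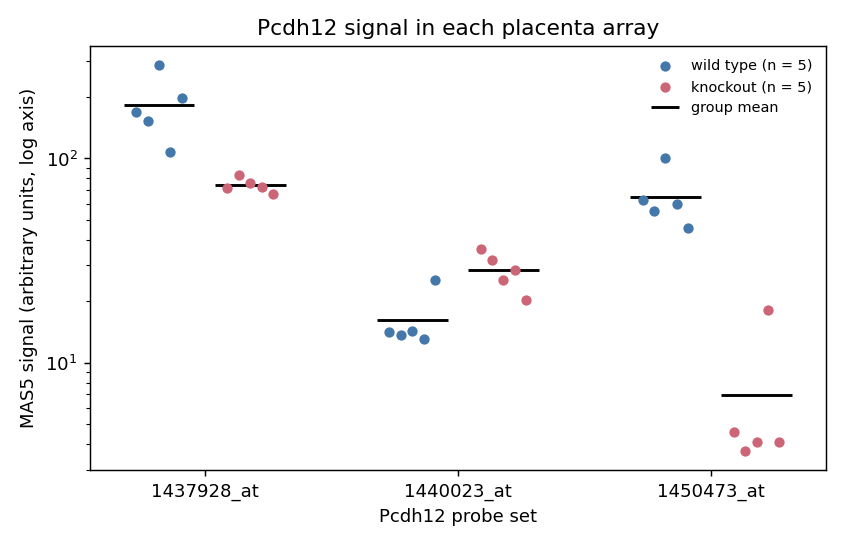
Signal of the 3 Pcdh12 probe sets (horizontal axis) in each array on a log axis (MAS5 signal, arbitrary units), with a point per array and a line at the mean of each group of 5. On 1437928_at the knockout arrays lie between 66.8 and 83.1 and the wild-type arrays between 108.1 and 286, and on 1440023_at the order of the groups is the opposite.

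Adamdec1, Rnase2a and Ang2 had the 3 largest increases in the knockout placentas at each of the 3 pseudocounts, and the order of the genes below them depended on the pseudocount. Adamdec1, a secreted metalloprotease of the ADAM family, rose from 8.9 ± 11.3 to 1600 ± 445 (log2 fold change 6.07, SE 0.25). Rnase2a, an eosinophil-associated ribonuclease, rose from 98.8 ± 81.6 to 4460 ± 888 (5.68, SE 0.46). Its relatives Ang2, an angiogenin (3.93, SE 0.19), and Ear3 (2.94, SE 0.17) rose as well, from signals of 2.72 ± 2.37 and 2.58 ± 3.5 that were close to the lowest on the arrays. Ear3 was read from a probe set ending in _x_at, and probe sets of this family can share signal between paralogs. The wild-type means of Adamdec1, Ang2, Ear3 and Slc15a2 lay below 13.6 units, the level of the filter, so the size of their changes is uncertain. In all, 2582 of 27022 probe sets were called (1276 higher and 1306 lower in knockout), which made 1393 of 12713 genes (753 higher and 640 lower). A change of at least 2-fold was seen for 149 of the higher and 32 of the lower genes.

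The rest of the 15 highest genes at the pseudocount of 16 rose by 1.81 to 3.16 log2 units. Prelp, a matrix proteoglycan, rose by 3.16 log2 units (SE 0.29) and stood above Ear3 and Slc15a2 at that pseudocount but below them at 1 (3.79 against 5.53 and 4.44). Sfrp4, a secreted modulator of Wnt signalling, rose by 2.15 (SE 0.38) and Antxr1, a receptor that binds matrix proteins, by 1.81 (SE 0.26). Il1r2, the decoy receptor of interleukin 1, rose by 2.10 (SE 0.21), from 267 ± 92.4 to 1170 ± 262, and Lbp, which binds bacterial lipopolysaccharide, rose by 2.15 (SE 0.44). Scgb1a1, a secretoglobin, rose by 2.30 (SE 0.32), Krtdap by 2.24 (SE 0.33), Tac2, the precursor of neurokinin B, by 2.12 (SE 0.39) and Psca by 1.94 (SE 0.49). The peptide transporter gene Slc15a2 rose by 2.31 (SE 0.29), but neither of its 2 other tested probe sets had the same sign. Taf7, a subunit of the general transcription factor TFIID that lies near Pcdh12 on chromosome 18, rose by 1.95 (SE 0.14), and 1 of its 2 other probe sets had the same sign.

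The 15 lowest genes fell by 1.20 to 2.32 log2 units. Slc39a2, a zinc transporter, fell by 2.32 log2 units (SE 0.40), from 340 ± 222 to 43.1 ± 13.5. Efhd2, a calcium-binding protein, fell by 2.10 (SE 0.13), from 1200 ± 216 to 264 ± 31.9. The kallikrein Klk4 fell by 2.05 (SE 0.31) and the serine protease gene Prss22 by 1.29 (SE 0.31). Suv39h2, a histone methyltransferase, fell by 2.02 (SE 0.26), Esco1, which acetylates cohesin, by 1.64 (SE 0.16) and H3f3b, which encodes histone H3.3, by 1.46 (SE 0.22). Mid1 fell by 2.00 (SE 0.52), Noct by 1.69 (SE 0.27), Hopx by 1.44 (SE 0.22), Tmem14c by 1.41 (SE 0.35), Nmrk1 by 1.39 (SE 0.18), Mtm1 by 1.37 (SE 0.17), Psg16 by 1.21 (SE 0.20) and Adi1 by 1.20 (SE 0.30). Neither of the 2 other probe sets of Nmrk1 had the same sign. Knockout signals of Mid1, Adi1 and Suv39h2 went down to 3.1, 4.2 and 9.3 units. These lie below 13.6 units, the level of the filter, so the size of these falls is uncertain.

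**Figure D2:**
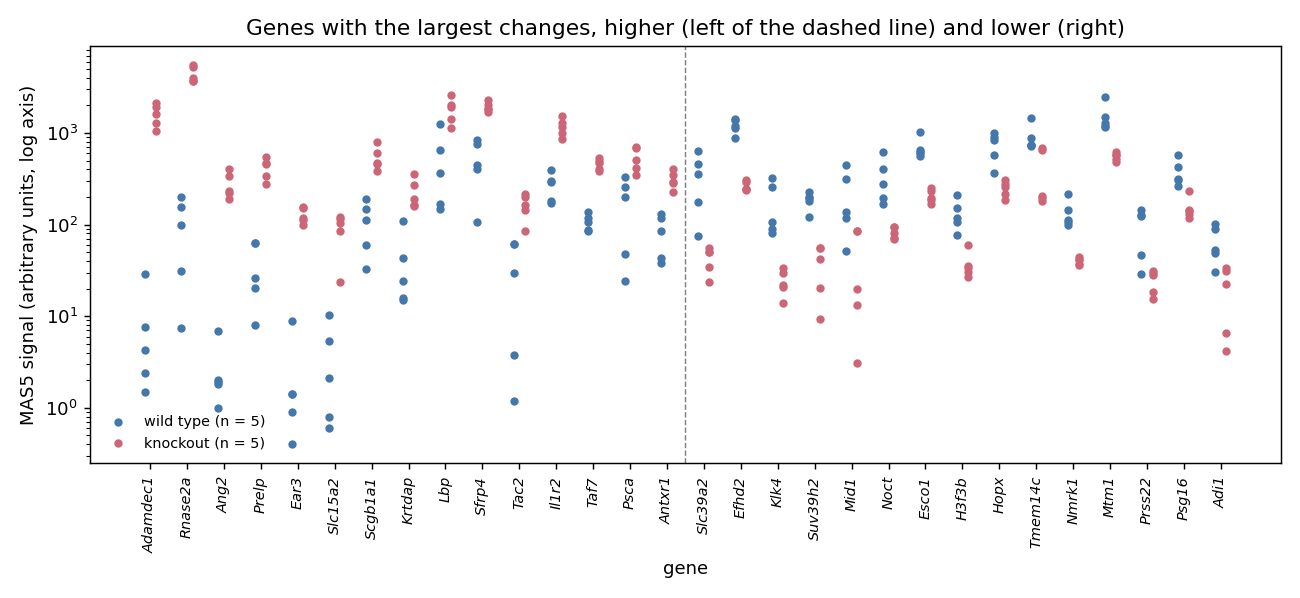
Signal in each array (vertical log axis, MAS5 signal, arbitrary units) of the 15 called genes with the highest and the 15 with the lowest log2 fold change (horizontal axis), with a point per array and 5 arrays per group. For Adamdec1 the knockout mean of 1600 stands against a wild-type mean of 8.9, and for Efhd2 a knockout mean of 264 stands against 1200.

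The counts of calls depended on single arrays and on how batches were treated. Without knockout replicate 1, 2 or 4 in turn, 1403, 1425 or 1201 probe sets and 756, 777 or 636 genes were called. With the wash run as a block 1008 probe sets and 537 genes were called, and with the chip lot as a block 254 and 134. Within the 2 wash runs the fits called 591 and 18 probe sets, and within the 2 chip lots 6 and 2609, the latter against 1 wild-type array. Among the genes above, leaving out 1 array ended the call of Psca (adjusted p = 0.0629, 0.0526 and 0.0654 without knockout replicates 1, 2 and 4), Tmem14c (0.0638, 0.0624 and 0.0668 without the same arrays) and Prss22 (0.0557 without knockout replicate 4 and 0.0517 without wild-type replicate 5). It also ended those of Adi1 (0.0581 and 0.0588 without knockout replicates 1 and 2, 0.0554 without wild-type replicate 5) and Mid1 (0.0729, 0.0627 and 0.0784 without knockout replicates 2, 3 and 4, 0.0615 and 0.0666 without wild-type replicates 4 and 5).

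Genes of the basement membrane, mesenchyme and blood vessels were higher in the knockout placentas. Of the 14 basement membrane and matrix genes tested, 12 rose (8 to 13 with 1 array left out, 13 adjusted over the list alone), with a mean log2 difference of 0.99 (95% interval 0.478 to 1.496). Agrn, a heparan sulfate proteoglycan, rose 2.44-fold, Lamc1 2.3-fold and Lama5 2.26-fold, both laminin chains, and Col18a1 2.02-fold. Of 14 mesenchyme and smooth muscle genes, 7 rose (7 to 11 with 1 array left out, 10 adjusted over the list alone) and all 14 had a positive log2 fold change, with a mean of 0.94 (0.52 to 1.36). These included the type I collagen genes Col1a1, up 2.84-fold, and Col1a2, up 2.79-fold, the pericyte receptor gene Pdgfrb, up 2.39-fold, and Acta2, the actin of smooth muscle, up 1.92-fold. Of 20 endothelial genes, 11 rose (7 to 12 with 1 array left out, 15 adjusted over the list alone), with a mean of 0.55 (0.36 to 0.74). Cdh5, the cadherin of endothelial junctions, rose 2.11-fold, from 496 ± 157 to 1020 ± 108, and Eng, Icam2 and Ptprb rose 1.76-fold, 1.77-fold and 1.77-fold. Each of the 3 lists passed the exact permutation test of list means (adjusted p = 0.0206) and camera at the preset correlation. None passed camera with an estimated correlation (adjusted p = 0.198, 0.13 and 0.13 with an estimated correlation, in the order basement membrane, mesenchyme and endothelium).

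Angiogenic genes and cadherins, which share some members with the endothelial list, shifted the same way. Of 22 angiogenic ligands and receptors 7 rose (3 to 8 with 1 array left out, 11 adjusted over the list alone), with a mean of 0.47 (0.29 to 0.65; adjusted p = 0.13 with an estimated correlation). Flt4, a receptor of lymphatic growth factors, rose 2.47-fold and Kdr, the main VEGF receptor of endothelium, 1.58-fold. Nrp2 rose 1.79-fold on its brightest probe set, and its 2 other probe sets had the opposite sign. Of 18 cadherins, protocadherins and catenins other than Pcdh12, 4 rose (2 to 8 with 1 array left out, 12 adjusted over the list alone), among them Cdh5 and the desmosomal gene Dsp, up 1.67-fold (list mean 0.47, adjusted p = 0.191 with an estimated correlation). Of 14 matrix proteases and inhibitors 6 rose (3 to 6 with 1 array left out, 7 adjusted over the list alone), among them Mmp14, a membrane-bound collagenase, up 2.03-fold, and Adam12, up 1.84-fold. That list passed camera with a mean of 0.45 (adjusted p = 0.251 with an estimated correlation), but its means did not pass the exact permutation test (adjusted p = 0.0774).

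Within the wash runs and chip lots these lists kept a positive difference, which for matrix proteases was 0.05 and 0.72 in the 2 runs and 0.27 and 0.72 in the 2 lots. The differences within a lot rest on 1 knockout array in the first lot and on 1 wild-type array in the second. For mesenchyme it was 0.61 and 1.25 in the 2 wash runs and 0.82 and 1.22 in the 2 chip lots, and 0.93 and 1.01 with wash run and chip lot as blocks. For basement membrane these values were 0.92, 1.04, 0.91 (first lot), 1.08, 0.98 and 0.99, and for endothelium 0.50, 0.61, 0.40, 0.69, 0.56 and 0.54, in the same order. The decidua list also differed between the groups (mean 0.69), and with its mean as a covariate the differences were 0.68 (95% interval 0.20 to 1.16) for mesenchyme, 1.21 (0.56 to 1.86) for basement membrane, 0.49 (0.23 to 0.75) for endothelium and 0.44 (0.18 to 0.69) for angiogenic genes. With that covariate the matrix protease list was not called by camera (0.14, interval -0.21 to 0.49), and 9 of the 17 called lists other than decidua were still called. All 18 lists called by camera kept their direction with either block, and 16 of them, all but the macrophage and proliferation lists, did so within each run and lot. Over the 26 lists camera called 18, with 15 higher and 3 lower in knockout, and the exact permutation test of list means called 15. In 6 of 100 splits of the 10 arrays, the real one included, camera called at least as many lists.

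**Figure D3:**
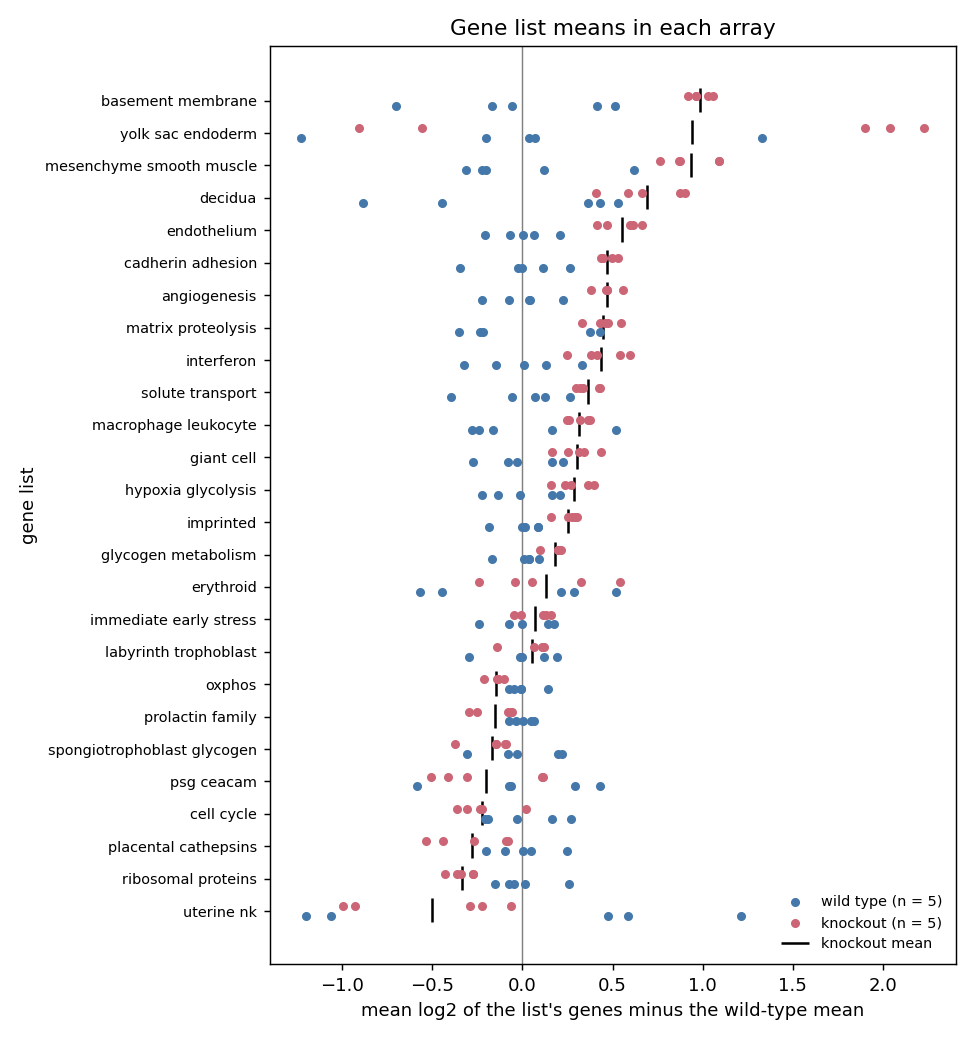
Mean log2 value of each gene list's tested genes in each array minus the wild-type mean (horizontal axis, log2 units), with 1 row per list, a point per array, 5 arrays per group and a line at the knockout mean. The knockout arrays lie between 0.92 and 1.06 for the basement membrane list, all above the wild-type arrays, and are spread from -0.91 to 2.23 for the yolk sac list.

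Trophoblast genes showed mixed changes. In the junctional zone list, which marks spongiotrophoblast and glycogen trophoblast, 2 of 14 genes fell (1 to 3 with 1 array left out, 3 adjusted over the list alone) and the list was not called (mean -0.17, 95% interval -0.43 to 0.08). Phlda2, an imprinted gene that restrains placental growth, fell by 0.98 log2 units (SE 0.10), from 2250 ± 169 to 1130 ± 114. Prl7b1, a placental prolactin, fell by 0.78 (SE 0.21), and this call was lost without knockout replicates 1, 3 or 4 (adjusted p = 0.0756, 0.0747 and 0.0813) or wild-type replicates 2 or 4 (0.0686 and 0.0585). Of 16 prolactin family hormones, 4 fell and 1 rose (1 to 4 and 1 to 2 with 1 array left out, 4 and 2 adjusted over the list alone). Prl8a1 was the one that rose, 2.01-fold, from 437 ± 74.7 to 926 ± 322. The prolactin list mean was -0.15 (exact permutation adjusted p = 0.0413), although camera did not call it (adjusted p = 0.129). Its genes Prl8a2, Prl3c1 and Prl6a1 are also in the decidua list, which marks maternal stroma. Without these 3 genes the difference was -0.05, so much of the fall came from genes that also count as decidual. Of 14 pregnancy-specific glycoprotein and Ceacam genes 3 fell and 1 rose (1 to 4 and 1 with 1 array left out, 5 and 2 adjusted over the list alone). Psg16 fell by 1.21 log2 units and Ceacam11 by 0.78, the latter not called without knockout replicate 4 (adjusted p = 0.0502), while Ceacam1 rose 1.87-fold (list mean -0.20, interval -0.71 to 0.31).

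Of 8 giant cell markers 3 rose (1 to 3 with 1 array left out, 6 higher and 1 lower adjusted over the list alone), with a list mean of 0.30 (exact permutation adjusted p = 0.0344; adjusted p = 0.251 with an estimated correlation). Camera did not call the list with the mean over all probe sets of a gene (adjusted p = 0.0532). Limk1, a kinase of the actin cytoskeleton, rose 1.39-fold. None of the 7 placental cathepsins was called by limma (2 with an unadjusted p under 0.05, 0 to 1 called lower with 1 array left out, 2 lower adjusted over the list alone), and their mean of -0.28 (95% interval -0.56 to -0.009) passed fry (adjusted p = 0.037) but neither camera (adjusted p = 0.102) nor the exact permutation test (adjusted p = 0.085), with Cts3 at 1710 ± 736 in knockout and 3030 ± 1150 in wild type (limma adjusted p = 0.0928). Of 13 labyrinth and syncytiotrophoblast genes 1 fell and 1 rose (1 and 0 to 2 with 1 array left out, 1 and 4 adjusted over the list alone), with a mean of 0.05 (-0.17 to 0.28) and a median of -0.04. Tfrc, the transferrin receptor, was the one that fell, by 0.58 log2 units (SE 0.12).

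Markers of other tissues that a dissected placenta can hold varied between arrays. Of the decidua, uterine natural killer and yolk sac lists, only decidua passed the exact permutation test. Of 15 decidual and uterine stroma genes 4 rose and 2 fell (2 to 7 and 0 to 2 with 1 array left out, 10 and 2 adjusted over the list alone; list mean 0.69, exact permutation adjusted p = 0.0413, fry adjusted p = 0.0983; adjusted p = 0.356 with an estimated correlation). Esr1, the oestrogen receptor, rose 2.77-fold and Hoxa11, a homeobox gene of the uterus, 2.65-fold. Among those that fell, Prl6a1, a prolactin, fell by 0.96 log2 units, and was not called without knockout replicate 2 or wild-type replicate 5 (adjusted p = 0.0592 and 0.0542). Relative to the wild-type mean, the decidua list stood at -0.88 in wild-type replicate 3 and -0.45 in wild-type replicate 5, and above 0 in the other 8 arrays. None of 11 uterine natural killer genes was called (0 to 1 lower with 1 array left out, 0 adjusted over the list alone; unadjusted p for the smallest, Gzmf, 0.053 in limma), and the list mean of -0.50 had an interval from -1.69 to 0.69. Fitted with the decidua list as a covariate that mean was -1.65 (-2.15 to -1.15), and camera called it. Of 16 yolk sac endoderm genes 2 rose, the endocytic receptor genes Cubn and Lrp2 (0 to 3 with 1 array left out, 2 adjusted over the list alone), and 1 of the 2 other probe sets of Lrp2 had the opposite sign. The call of Cubn (adjusted p = 0.0491) was lost in 8 of the fits that left out 1 array, with adjusted p = 0.124, 0.125 and 0.111 without knockout replicates 1, 4 and 5 and 0.0635, 0.088, 0.0678, 0.0615 and 0.0904 without wild-type replicates 1 to 5. Lrp2 was not called without knockout replicates 1, 4 or 5 (adjusted p = 0.103, 0.102 and 0.0944) or wild-type replicates 2 or 5 (0.0869 and 0.0908). Both calls were also lost without an intensity trend (adjusted p = 0.0779 for Cubn and 0.0626 for Lrp2) and with the decidua list as a covariate (0.157 and 0.113). The yolk sac list passed camera (mean 0.94, adjusted p = 0.511 with an estimated correlation) but not the exact permutation test (adjusted p = 0.364). It was high in knockout replicates 1, 4 and 5 (1.90, 2.04 and 2.23 above the wild-type mean) and in wild-type replicate 4 (1.33), and camera no longer called it without wild-type replicate 3 (adjusted p = 0.0593), with the filter at the 70th percentile (adjusted p = 0.188) or with the decidua list as a covariate (0.28, interval -2.17 to 2.72).

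Of 14 macrophage and leukocyte genes 3 rose (2 to 4 with 1 array left out, 3 adjusted over the list alone), among them Csf1r, the receptor of colony stimulating factor 1, up 1.7-fold, and the lysozyme gene Lyz2, up 1.9-fold. The list passed camera (mean 0.31, adjusted p = 0.337 with an estimated correlation) but not the exact permutation test (adjusted p = 0.141). Its camera call ended without wild-type replicate 3 or 5 (adjusted p = 0.104 and 0.12), with the wash run as a block (adjusted p = 0.104) and with the filter at the 70th percentile (adjusted p = 0.138), and its difference was -0.03 within the first wash run. That difference was 0.07 (-0.30 to 0.45) over all arrays with the decidua list as a covariate, and camera did not call the list. Of 13 interferon response genes 4 rose (2 to 4 with 1 array left out, 6 adjusted over the list alone; mean 0.44, adjusted p = 0.241 with an estimated correlation), with Oasl2, an antiviral protein, up 1.85-fold and Bst2, which tethers virus particles, up 1.66-fold. The interferon difference was 0.17 (-0.03 to 0.37) with the decidua list as a covariate, and camera did not call it. No gene was called by limma among 11 fetal red blood cell genes (1 with an unadjusted p under 0.05, 0 adjusted over the list alone, mean 0.13, interval -0.46 to 0.72).

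Of the metabolic lists, 4 of 17 hypoxia and glycolysis genes rose and 1 fell (3 to 4 and 1 with 1 array left out, 6 and 1 adjusted over the list alone; mean 0.29, adjusted p = 0.251 with an estimated correlation). Hk2, a hexokinase, rose 2.71-fold, from 260 ± 78.3 to 722 ± 178, and Ndrg1 1.76-fold, while Pdk1, which inhibits pyruvate dehydrogenase, fell by 1.13 log2 units (SE 0.17). Camera did not call the hypoxia list with the decidua list as a covariate (0.10, interval -0.07 to 0.28). Of 21 solute and ion transporters 5 rose (2 to 6 with 1 array left out, 6 adjusted over the list alone), among them Abca1, a cholesterol transporter, up 1.9-fold (list mean 0.36, adjusted p = 0.251 with an estimated correlation). Among 25 imprinted genes 5 rose and 1, Phlda2, fell (2 to 6 and 1 with 1 array left out, 7 and 1 adjusted over the list alone). Cd81, a tetraspanin, rose 1.85-fold and Ndn 1.6-fold (list mean 0.26, adjusted p = 0.241 with an estimated correlation), and with the chip lot as a block the list was not called (0.18, camera adjusted p = 0.0517). Of 16 genes of glycogen synthesis and breakdown 1 rose (1 with 1 array left out, 1 adjusted over the list alone), Ppp1r3c, a phosphatase subunit that promotes glycogen storage, up 1.64-fold (list mean 0.18, adjusted p = 0.198 with an estimated correlation). The decidua covariate left the glycogen list not called by camera either (0.20, interval 0.04 to 0.36), as did the filter at the 70th percentile (adjusted p = 0.0559) and the mean over all probe sets of a gene (adjusted p = 0.0558).

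Of 14 ribosomal protein genes 8 fell (3 to 8 with 1 array left out, 11 adjusted over the list alone), with a mean of -0.34 (exact permutation adjusted p = 0.0206; adjusted p = 0.241 with an estimated correlation). Rps3 fell by 0.49 log2 units (SE 0.11), from 6570 ± 983 to 4630 ± 202, and Rps18 by 0.51 (SE 0.12). Of 20 genes of oxidative phosphorylation 2 fell (0 to 4 with 1 array left out, and 0 in 6 of those 10 fits; 4 lower and 1 higher adjusted over the list alone), with a mean of -0.15 (exact permutation adjusted p = 0.0206; adjusted p = 0.276 with an estimated correlation). Of 21 proliferation genes 4 fell (0 to 4 with 1 array left out, and 0 without knockout replicate 1 or 4; 4 adjusted over the list alone), and that list passed camera (mean -0.22, 95% interval -0.49 to 0.04, adjusted p = 0.337 with an estimated correlation) but not the exact permutation test (adjusted p = 0.138). Cdk1, the main kinase of mitosis, fell by 0.50 log2 units, and was not called without knockout replicates 1, 2 or 4 (adjusted p = 0.0539, 0.0547 and 0.0522). Within the first chip lot the proliferation list was 0.09 higher in knockout. With the decidua list as a covariate camera called neither the proliferation list (-0.000495, interval -0.21 to 0.21) nor that of oxidative phosphorylation (-0.12, -0.245 to 0.01), while the ribosomal list was still called (-0.39, -0.63 to -0.15). Immediate early and heat shock genes went both ways, with 4 of 15 risen and 2 fallen (1 to 4 and 0 to 5 with 1 array left out, 5 and 5 adjusted over the list alone), a mean of 0.07 and a median of -0.06. Fos, an immediate early transcription factor, rose 1.73-fold.

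In the main window around Pcdh12 the share of called genes did not differ detectably from that elsewhere. Among the 100 protein-coding neighbours on each side, 13 of 88 tested genes were called (14.8%), 10 higher and 3 lower, against 10.9% of the genes elsewhere (odds ratio 1.41, 95% interval 0.72 to 2.58, Fisher's exact two-sided p = 0.232). With 50 neighbours on each side the odds ratio was 1.88 (95% interval 0.63 to 4.68, exact p = 0.155), and with 200 it was 1.54 (exact p = 0.0224). At 100 neighbours it was 1.90 (exact p = 0.0445) without knockout replicate 3 and 2.01 (exact p = 0.036) without wild-type replicate 5.

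The groups did not differ detectably in RNA quality or in embryo sex. The ratio of 3-prime to 5-prime Gapdh signal was 0.701 ± 0.0166 in knockout and 0.69 ± 0.0334 in wild type (SD, n = 5 each; exact two-sided permutation p = 0.524), and that of Actb was 1.29 ± 0.0479 and 1.32 ± 0.145 (exact p = 0.921). Both groups held arrays with high and low signal of Y-linked genes, with a mean log2 value of 5.13 ± 0.823 in knockout and 5.22 ± 0.901 in wild type (exact p = 0.786). The signal of Eif2s3y ran from 0.3 to 109.4 in knockout and from 1.1 to 178.9 in wild type. Xist, the RNA that silences an X chromosome, differed by 0.07 log2 units (exact p = 0.952). Uty differed by -0.17 log2 units (exact p = 0.738) and Kdm5d by -0.05 (exact p = 0.889).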

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

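The tests with the decidua list as a covariate and the tests of closeness between strongly changed genes were chosen after the result was seen. In each group of 5 arrays a value was marked when its gap to the nearest array exceeded 0.71 of the group's range. This marked 18 of 330 groups, where chance alone marks about 1 in 20, or 16.5.

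Among the Pcdh12 probe sets, knockout replicate 4 was high on 1450473_at (gap 0.919 of the range; log2 value 5.09 against 4.30 to 4.36) and wild-type replicate 5 was high on 1440023_at (0.886). Wild-type replicate 4 was high for Ang2 (0.808), Esco1 (0.743) and the Actb 3-prime to 5-prime ratio (0.898; 1.58 against 1.23 to 1.27), and low for Gys1 (0.74) and Irf7 (0.725). Wild-type replicate 3 was high for Ear3 (0.857) and Tmem14c (0.73), and wild-type replicate 5 was high for Btg2 (0.712). Knockout replicate 2 was low for Slc15a2 (0.764; log2 value 5.31 against 6.67 to 7.09). Knockout replicate 5 was low for Cdh3 (0.85) and the labyrinth list (0.785) and high for Cdk1 (0.785). Knockout replicate 3 was low for Fat1 (0.763) and the glycogen metabolism list (0.863) and high for Cox4i1 (0.725). Knockout replicate 4 was low for the junctional zone list (0.809).

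The mesenchyme list was 0.94 log2 units higher in knockout, the group that the design names. A difference in RNA quality, as tracked by the Gapdh ratio, is argued against as its whole cause. With that ratio as a covariate the difference was 0.98 (95% interval 0.53 to 1.43), above 0.469, which is 0.5 of its value. The ratio had similar means in the 2 groups (0.701 in knockout and 0.69 in wild type), and the Actb ratio was not used as a covariate. More maternal tissue could account for part of the mesenchyme difference, since the decidua list was higher by 0.688 and 12 of its 15 genes had a positive log2 fold change. The uterine natural killer list was not higher (-0.50, interval -1.69 to 0.69). The 2 brightest decidua genes, Prl8a2 (15000 ± 1090 against 17600 ± 3730) and Prl6a1 (2650 ± 1020 against 4870 ± 841), were not higher either. The next in brightness, Cryab, Des, Hand2 and Pgr, had log2 fold changes of 1.21, 0.92, 1.21 and 1.27, with Des and Pgr not called. Of the 15 decidua genes, 3 are held by other lists and 0 by the mesenchyme list. With the decidua list as a covariate the difference was 0.681 (0.20 to 1.16), with wash run as a block 0.931 (0.43 to 1.43) and with chip lot as a block 1.01 (0.38 to 1.65), and since these intervals reach below 0.469, maternal tissue and batch cannot be told apart from genotype as a part of the cause. A biological effect of the knockout stays open as a hypothesis.

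Called genes were not clearly concentrated near Pcdh12, with an odds ratio of 1.41. A flanking segment of another strain, carried along with the targeted allele, could raise the odds, but the interval of 0.72 to 2.58 includes both no excess and more than a doubling. The labels used here name no strain, so this explanation cannot be told apart from chance or from an effect of the knockout.

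Of the 45 strongly changed genes (at least 1.5 log2 units) with a place in the reference, 12 pairs lay within 50 protein-coding genes of each other, against a median of 5 in 10000 permutations (one-sided permutation p = 0.0067). This was tested because Adamdec1, Rnase2a, Ang2 and Slc39a2 had been seen to lie on chromosome 14, where 6 of the pairs lie, so the p does not come from an independent question. Without these and Rnase4, 40 genes and 6 pairs were left against a median of 4 (permutation p = 0.177), which neither argues for strain variants in segments across the genome nor excludes them. With 1 gene per symbol stem and no probe sets ending in _x_at or _s_at, 36 genes and 4 pairs were left against a median of 3 (permutation p = 0.36). This step also removed genes that were not paralogs of their neighbours. The zinc transporter gene Slc39a2, which fell, was dropped because it shares its stem with Slc15a2. Its pairs with Ang2, Rnase2a and Rnase4, which rose, went with it. The loss of pairs therefore cannot tell signal shared between paralogs from the loss of other genes. Shared regulation of neighbours was not tested.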

How the results depend on the processing

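Fits within a wash run or chip lot, without 2 arrays and with the decidua list as a covariate were chosen after seeing the data. Of 106 called named genes and probe sets, 69 lost their call in no fit chosen in advance other than the blocks. None changed sign in any fit that tested it. Genes left out by the filter at the 70th percentile were not tested there. The exact rank sum test and the other probe set rules were followed by counts alone, so the 69 does not cover them. The chip lot block ended 70 of the 106 calls, the wash run block 36 and the decidua covariate 29. The 2 scalings moved the median difference of all probe sets by less than 0.1 log2 units (-0.0115 centred on the median, -0.0244 with quantile normalization, -0.0295 as deposited). Against 2582 probe sets and 1393 genes, the wash run as a block left 1008 and 537 (954 of the former shared) and the chip lot as a block 254 and 134 (252 shared). The first and second wash runs alone called 591 and 18 probe sets and 307 and 8 genes, the first chip lot 6 and 2, and the second, with 1 wild-type array, 2609 and 1460, and the cause of these differences was not tested. The exact rank sum test called 0 probe sets (5418 at an unadjusted p under 0.05). Its smallest p of 0.00794 passes the adjustment only where enough probe sets reach it, and too few did. Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05), against 18 by preset correlation. The filter at the 70th percentile called 15, without yolk sac, macrophage and glycogen metabolism, the mean over all probe sets 16, without giant cell and glycogen metabolism, and fry 16, without decidua, yolk sac, macrophage and proliferation. Of the 18, the chip lot block ended the imprinted call and the wash run block the macrophage call. With the decidua list as a covariate 10 lists (9 shared), 2857 probe sets (1518 shared) and 1601 genes were called, with Pcdh12 at -0.69. The Pcdh12 call was lost with the chip lot as a block (-1.19, adjusted p = 0.0523), in the second wash run (-1.18, adjusted p = 0.46) and in the first chip lot (-1.16, adjusted p = 0.949), where 1 knockout array is assumed to vary like the others, and adjusted p elsewhere ran from 0.000688 to 0.0352. The cause of these losses was not tested. With 200 neighbours the odds ratio near Pcdh12 passed the threshold (1.54). Leaving out 1 array gave 1201 to 2905 probe sets, 636 to 1593 genes, 17 to 20 lists, Pcdh12 from -1.24 to -0.91, odds ratios of 1.21 to 2.01, Gapdh differences of 0.0023 to 0.0428 and Actb differences of -0.0449 to 0.0432 (log2 ratios), and Y-linked differences of -0.32 to 0.19. Of lists and genes called in either fit, direction turned for the macrophage list in the first wash run (-0.0302), for the proliferation list in the first chip lot (0.0852), and in the second chip lot, with 1 wild-type array, for the fetal red blood cell list (-0.47), the uterine natural killer list (0.87), Gzmc (0.70), Gzme (0.81) and Gzmf (0.43), and the cause was not tested. Of lists called in neither fit it turned for labyrinth with the chip lot as a block (-0.07), in both chip lots (-0.11 and -0.02), without wild-type replicate 4 (-0.02) and without 2 arrays (-0.03), for immediate early genes in the first wash run (-0.02), the first chip lot (-0.05) and with the decidua covariate (-0.01), for the red blood cell list without wild-type replicate 1 (-0.01), and with that covariate for the junctional zone (0.02) and pregnancy-specific glycoprotein (0.06) lists. The replicate number showed no clear pairing of the arrays, although so few arrays cannot exclude one. Deviations of same-numbered arrays correlated between -0.007 and 0.12, and 2 of 5 knockout arrays correlated best with their own number. The replicate block called 2541 probe sets, 1378 genes and 20 lists, with Pcdh12 at -1.08 and limma adjusted p = 0.0042. No detection calls were used here, so how far dim signals such as those of Ang2 and Ear3 in wild type lie above background is unknown.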

Other observations

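The tests over other splits of the arrays were planned, and the genes below were chosen after their values were seen. Besides Pcdh12, 47 called genes changed by at least 1.5 log2 units, 40 higher and 7 lower in knockout. Single higher genes not yet described included Lum at 1.75, Emilin2 at 1.76, Plod2, which modifies collagen, at 1.68 and Fbln5 at 1.64 log2 units. Col5a1 at 1.59, Col5a2 at 1.54 and Col6a3 at 1.53 were also among them. So were Rbm45 at 1.805, 6330403K07Rik at 1.79, Padi2 at 1.74 and Tmem176a at 1.64, and the list given here is not complete. Aqp1, a water channel of endothelium, was higher by 1.63, the complement inhibitor gene Serping1 by 1.67 and H2-Ab1, a class II histocompatibility gene, by 1.67. Near Pcdh12, Arap3, a regulator of small GTPases in vessels, was higher by 1.25 and Gnpda1 by 0.73.

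Wild-type placentas varied more than knockout placentas. The median SD of a probe set was 0.274 log2 units in wild type and 0.202 in knockout, and it was larger in wild type for 68.4% of probe sets. Correlations between arrays ran from 0.969 to 0.976 within knockout and from 0.934 to 0.973 within wild type. The first principal component held 31.8% of the variance and parted the groups (-36.9 to -22 in knockout, 10.8 to 53 in wild type), while the second (19.6%) set wild-type replicates 2 and 4 (20.8 and 44.8) against 3 and 5 (-45.9 and -33).

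Chance alone is argued against for the counts of probe sets and genes. Of 100 splits of the 10 arrays drawn from 126, only 1, the real one, called as many probe sets (2582, with 1 as the highest of the others) or as many genes (1393, with 1 as the highest of the others). The splits cannot tell genotype from chip lot, which was uneven between the groups, and with the lot as a block 254 probe sets were called. For the count of lists chance stays possible, since 6 splits, the real one included, called as many as the real 18 and the highest of the others called 20.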
